A study of Mus musculus with 18 samples.

How the data were processed

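RNA was measured in mural granulosa cells, which line the wall of the ovarian follicle, and in cumulus cells, which surround the oocyte, taken from mouse ovaries 0, 4 and 12 h after an injection of human chorionic gonadotropin (hCG). Per the labels, RNA came from the RNeasy Micro and Mini kits and libraries were made with a stranded mRNA kit and run on an Illumina instrument. The series' design text adds enrichment for polyadenylated RNA. There were 18 libraries, 3 in each of 6 groups. Libraries were grouped by their titles. The cell-type characteristic did not match them: of the 9 titles that name cumulus cells, 8 carried the mural cell type and 1 carried none. The markers reported for the untreated groups followed the titles.

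Values were the deposited raw integer counts of uniquely mapped reads per gene, in 1 table of 41325 entries. Per the series' design text, alignment and counting were done in CLC Genomics Workbench with default parameters. Its version, gene annotation and strand setting are not given in the sources used here. The submitters' processing notes name the genome build GRCm38. All columns were used and every entry had a name. Of the gene names, 40826 occurred in the mouse reference annotation (GENCODE M21, GRCm38). A number suffix on 153 names separates entries of one name, kept apart. Of the 430 genes on the fixed lists, 427 were in the table.

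Libraries held 32.2 M to 47.9 M counts (M for mega), on average 38.4 M. A count of 3 in one library, which is the upper limit that a count of 0 allows, corresponded to between 0.0626 and 0.0931 counts per M counts (CPM). Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

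Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by edgeR's expression filter with a minimum count of 10, which left 19941 genes holding 99.96% of the reads. Counts were scaled by the trimmed mean of M values (TMM, factors from 0.849 to 1.177), and CPM values use these scaled totals. One quasi-likelihood negative binomial model with a mean for each of the 6 groups was fitted to the 18 libraries with robust estimation of the spread. From it came 11 comparisons: each pair of times within a cell type, cumulus against mural cells at each time, and the difference between the cell types' changes from 0 to 4 h and from 0 to 12 h. Each adjusted p of a gene comes from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05. A gene past it is called. Fold changes are given on the log2 scale with their standard error (SE), levels as mean CPM with the standard deviation (SD) over 3 libraries. Nothing in the labels says that libraries of one group came from separate animals or pools, so p-values measure the spread between these samples, which may be technical. The spread between each pair of libraries of one group nevertheless exceeded counting error (lowest chi-square per degree of freedom 8.35). It was unequal between groups and reached 273 in cumulus cells at 4 h and 82.9 in those at 0 h. In mural cells it was at most 40.4, and in cumulus cells at 12 h at most 12.8. The fit shares a single spread per gene over the groups, so SE and adjusted p with cumulus cells at 4 h may be too small. Across genes, correlations of log2 CPM within groups ran from 0.946 to 0.99, and genes are not independent replicates.

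Gene lists came from textbook knowledge: 23 of pathways, 1 of mitochondrially encoded transcripts and 10 of cell-type markers. Each list with at least 3 genes tested was compared with the other genes by limma's camera with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and the fry test were run beside it. Members were counted as higher, lower or not called over all genes tested, and again "adjusted over the list alone". Groups, model, comparisons, threshold, lists, the rule for named genes and the first set of alternatives were chosen before the data were examined.

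Named genes followed that rule. It takes 24 key genes of ovulation, and for each comparison the 5 largest rises and 5 largest falls among called genes with a mean of at least 20 CPM in the higher group and no overlap between the groups, leaving out clone and predicted names. It adds up to 4 members with the largest change from each list that was called. For 12 against 4 h and for the differences between cell types it takes only called key genes and the 5 and 5 largest. A second set of 5 and 5 without genes that follow oocyte RNA was added after the data were seen, as were members of a list named to show its counts.

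A fold against a group with no counts is given as at least the ratio to a floor of 3 counts over that group, and with 1 to 3 counts as the ratio with its 95% exact interval. Oocyte RNA was followed by the summed CPM of 15 measured oocyte markers. A gene was called oocyte-linked where, within groups, its level rose with that sum (t over 3 with 11 residual degrees of freedom) and where the fitted line put at least 20% of its level on the sum in some group. This step was chosen after the data were seen and marked 4104 genes.

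The pipeline was tested on simulated counts for the comparison of cumulus cells at 4 and 0 h, drawn for 19941 genes from the means, spreads and totals of these libraries. It recovered 49% of 100 genes changed 2-fold and 74% of 100 genes changed 4-fold, with median absolute log2 changes of 0.99 and 1.97. It made 3 false calls, 2.38% of its calls, and 0 calls in the unchanged simulated mural comparison. Camera called a simulated list of 20 raised genes and did not call one of 20 unchanged genes. Genes were drawn independently and few changed, so the preset correlation and scaling under many changes stay untested.

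Alternatives planned at the outset were DESeq2 size factors or library totals in place of TMM, DESeq2's own test, limma-voom, no filter on low counts, a filter on mean CPM, only the groups compared in the fit, thinning to one depth, a 2-fold minimum, the replicate number as a block and leaving out each library in turn. Added after the data were seen were the log2 oocyte marker sum as a covariate, the fit without oocyte-linked genes, the fit without mitochondrially encoded genes, and the fit without a pair of libraries that stood apart (cumulus 0 h replicate 1 and cumulus 4 h replicate 3). The covariate is built from the oocyte markers, so it cannot test their own list. Gene positions were read from the annotation for 278 named genes, of which 277 matched once. An exon was shared with another coding gene for 35 of them (for example Junb with Prdx2), and the strand setting of the counting is unknown, so these counts are uncertain. Close paralogs (the globins Hba and Hbb, Fbxw16 and Fbxw21, Sprr2g, Tuba3a) are uncertain too. Results of some of the named genes are not reported here. Splicing, isoforms and reads outside genes were not analysed here.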

Results

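Mural granulosa and cumulus cells of the mouse ovary were followed through ovulation, in 3 libraries each at 0, 4 and 12 h after hCG. This hormone acts on the luteinizing hormone (LH) receptor and triggers ovulation. The mural libraries held 47.9 M, 34.9 M and 38.9 M unique gene counts at 0 h, 32.2 M, 37.1 M and 36.9 M at 4 h, and 35.1 M, 38.3 M and 40.1 M at 12 h. The cumulus libraries held 37.3 M, 43.7 M and 37.8 M at 0 h, 44.7 M, 34.4 M and 35.7 M at 4 h, and 37.3 M, 36.9 M and 41.3 M at 12 h. The first 3 principal components of the log2 values took 40.3, 21.7 and 15.8% of the variance. The 3 cumulus libraries of 12 h lay at one end of the first component, between 134.9 and 136.9, and those of 0 h toward the other, between -153.7 and -100.5, with replicate 3 of the cumulus cells at 4 h at -138.3. Log2 changes are given ± SE (n = 3 libraries per group), and list medians are of log2 changes. Lists can share genes, as estradiol and granulosa identity do, so their calls are not independent. Where a list has no separate count adjusted over the list alone, that count was the same.

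The summed level of 15 oocyte markers varied widely between libraries. It was 460, 2147 and 2224 CPM in the cumulus libraries of 0 h, 2530, 1318 and 8087 CPM in those of 4 h, and 9.19, 12.6 and 6.79 CPM in those of 12 h. In mural libraries it ran from 143.3 CPM at 12 h to 676 CPM at 0 h. The share of counts from mitochondrially encoded genes was 12.8, 8.49 and 8.5% in cumulus cells at 0 h, 6.2, 4.35 and 5.76% at 4 h and 2.52, 2.54 and 2.98% at 12 h. Mural libraries lay between 3.54 and 7.57%. Cumulus 0 h replicate 1 had the highest mitochondrial share and cumulus 4 h replicate 3 the highest oocyte sum. Counts of genes are therefore given also without these 2 libraries, where a comparison holds one, and outside 4104 oocyte-linked genes, both chosen after the data were seen.

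**Figure D1:**
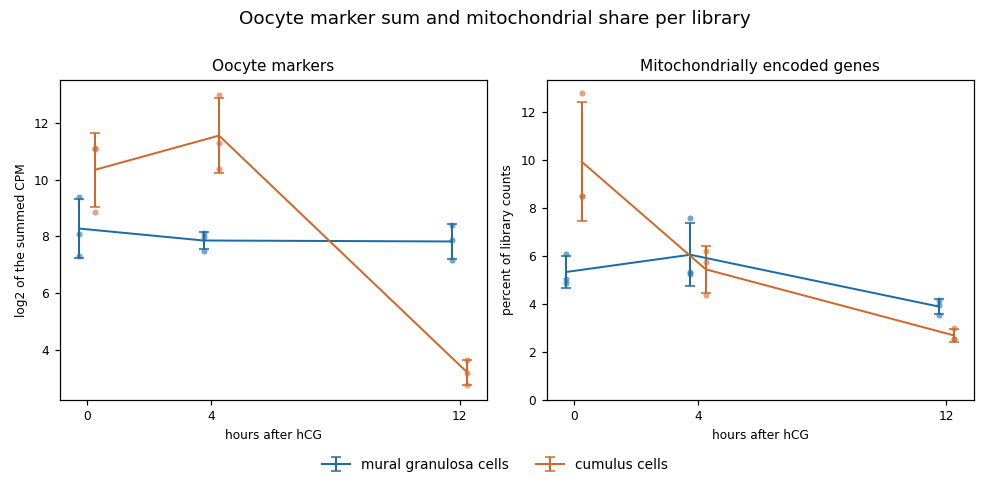
Oocyte RNA and mitochondrial transcripts per library. The left panel shows the log2 of the summed CPM of the oocyte markers and the right panel the percent of counts from mitochondrially encoded genes, with 1 point per library in the 6 groups. The cumulus libraries of 12 h lie lowest in both, at 6.79 to 12.6 CPM and 2.52 to 2.98%.

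Genes named most often lie at these positions in GRCm38 (GENCODE M21, each protein-coding). The EGF-like growth factor genes Areg (chromosome 5, 91139599 to 91148432), Ereg (5, 91074622 to 91093646) and Btc (5, 91357261 to 91402994) lie close together. Ptgs2 spans 150100031 to 150108227 on chromosome 1 and Has2 spans 56665627 to 56694539 on 15. Ptx3 spans 66219910 to 66225805 on 3, Tnfaip6 spans 52038009 to 52056686 on 2, and Snap25 spans 136713453 to 136782428 on 2. Lhcgr (17, 88716481 to 88791990) and Fshr (17, 88984952 to 89200675), the receptors of LH and of follicle-stimulating hormone, are neighbours. Cyp11a1 (9, 58006411 to 58027023), Cyp19a1 (9, 54165937 to 54268110) and Star (8, 25806555 to 25815982) serve steroid synthesis. Pgr spans 8899833 to 8968611 on 9 and Edn2 spans 120161206 to 120167360 on 4.

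Mural cells were first compared at 4 and 0 h. The EGF-like growth factors that relay the LH signal rose steeply. Areg went from 1.07 ± 0.327 to 406 ± 239 CPM, with Ereg (10.01 ± 0.46) and Btc (9.42 ± 0.29) beside it. Ptgs2, the inducible prostaglandin synthase, rose from 0.827 ± 0.325 to 2360 ± 1081 CPM (11.47 ± 0.59). The progesterone receptor gene Pgr went from 2.08 ± 0.121 to 1974 ± 570 CPM (9.88 ± 0.42). Genes of the hyaluronan matrix rose as well, with the synthase Has2 (7.22 ± 0.44) and the matrix organisers Ptx3 (10.53 ± 0.47) and Tnfaip6 (10.58 ± 0.35). Snap25, a SNARE protein of vesicle fusion, rose from 0.193 ± 0.0537 to 487 ± 45.3 CPM (11.25 ± 0.31). Star, which carries cholesterol into mitochondria, went from 21.6 ± 5.33 to 3113 ± 711 CPM (7.17 ± 0.28). The FSH receptor gene Fshr (-2.18 ± 0.2), the aromatase gene Cyp19a1 (-2.22 ± 0.26) and the C-type natriuretic peptide gene Nppc (-3.47 ± 0.3) fell. The adjusted p of each of these genes was at most 1.69e-06.

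Other key genes that rose were Runx1, Il6, Cebpb, Edn2, Adamts1 and Cyp11a1, at 1.53 to 5.1 (SE 0.13 to 0.55) (adjusted p at most 0.00359). Inhba and Amh, at -0.17 ± 0.26 and 0.62 ± 0.4, were not called (adjusted p = 0.648 and 0.229). Lhcgr, the receptor of hCG itself, was at -0.97 ± 0.4 with adjusted p = 0.0574, and passed the threshold in 8 alternatives, at -0.95 (replicate block) to -1.29 (library totals). The largest rises included the neuropeptide genes Nts (13.2 ± 0.38) and Npy, which went from 0 counts to 22.7 ± 6.58 CPM, at least 1030-fold. Sult1e1, an estrogen sulfotransferase, went from 3 counts over the 0 h group to 1465 ± 412 CPM, a ratio of 66700 (interval 22800 to 323000). Among the largest falls were Fam196b (-6.15 ± 0.47), Jakmip3 (-4.73 ± 0.3) and Rgs6 (-4.52 ± 0.24).

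Camera called 16 of the 34 lists, 12 up and 4 down, and 2 held with an estimated correlation. Of the EGF-like ligands and ERK feedback genes 9 of 14 rose and 2 fell (median 4.01, adjusted p = 5.14e-14, adjusted p = 0.0326 with an estimated correlation). Of ovulatory regulators 14 of 17 rose and 2 fell (median 2.95, adjusted p = 4.91e-19, adjusted p = 0.0338 with an estimated correlation). Among the immediate early transcription factors 14 of 18 rose (median 3.07, adjusted p = 5.80e-09, adjusted p = 0.267 with an estimated correlation), with Egr3 (9.12 ± 0.36). In the cumulus expansion matrix 12 of 17 rose and 2 fell (median 1.98, adjusted p = 1.54e-10, adjusted p = 0.177 with an estimated correlation). Of matrix proteases and inhibitors 11 of 20 rose and 3 fell (12 and 3 adjusted over the list alone, median 1.49, adjusted p = 1.81e-06, adjusted p = 0.151 with an estimated correlation), with Plaur (5.35 ± 0.34) and Timp1 (4.53 ± 0.15). Among cytokines and innate signals 12 of 21 rose (14 adjusted over the list alone, median 1.58, adjusted p = 0.000161, adjusted p = 0.0563 with an estimated correlation). In Notch signalling 6 of 12 rose and 1 fell (median 0.84, adjusted p = 0.0186, adjusted p = 0.177 with an estimated correlation), with Hey1 (4.35 ± 0.31) and Jag1 (4.33 ± 0.31). In progesterone synthesis 7 of 14 rose and 3 fell (7 and 4 adjusted over the list alone, median 0.5, adjusted p = 0.00492, adjusted p = 0.408 with an estimated correlation). Of estradiol and follicular-phase genes 9 of 14 fell (10 adjusted over the list alone, median -1.26, adjusted p = 3.04e-06, adjusted p = 0.276 with an estimated correlation), with Inhbb (-4.02 ± 0.27). Among granulosa identity genes 6 of 10 fell (7 adjusted over the list alone, median -1.02, adjusted p = 0.000112, adjusted p = 0.276 with an estimated correlation). Prostaglandin genes and regulated exocytosis were called up (adjusted p = 0.0136 and 0.023, adjusted p = 0.177 and 0.177 with an estimated correlation). Their medians of 0.23 and 0.08 turned negative with library totals, at -0.11 and -0.24, and that of exocytosis also without replicate 1 (-0.04) or replicate 3 (-0.01) of 4 h.

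Hypoxia signals and cell cycle brakes up, and mitosis and S phase down, were called weakly (adjusted p = 0.0265 to 0.0346, adjusted p = 0.38 to 0.651 with an estimated correlation). Without replicate 1 of 0 h the hypoxia, mitosis and S phase calls ended (adjusted p = 0.0571, 0.0624 and 0.0523). The hypoxia and brake calls ended with the oocyte sum as a covariate (0.0739 and 0.0707, medians from 1.1 and 0.3 to 1.03 and 0.42). They ended also without oocyte-linked genes (0.0614 and 0.0666, medians 1.11 and 0.63), and library totals turned the brakes' median to -0.03. The 6 erythroid markers were each higher (median 2.41), a list not called at adjusted p = 0.0504 but called in 3 alternatives (0.0292 to 0.0377). So were the 3 neutrophil markers measured (median 4.72, or 4.02 with genes at their bound), not called at 0.183. In total 8991 of 19941 genes were called, 4549 higher and 4442 lower (4224 and 3782 not oocyte-linked). With library totals in place of TMM the median of all genes moved from -0.06 to -0.38, and 29.1% instead of 50.6% of called genes were higher.

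**Figure D2:**
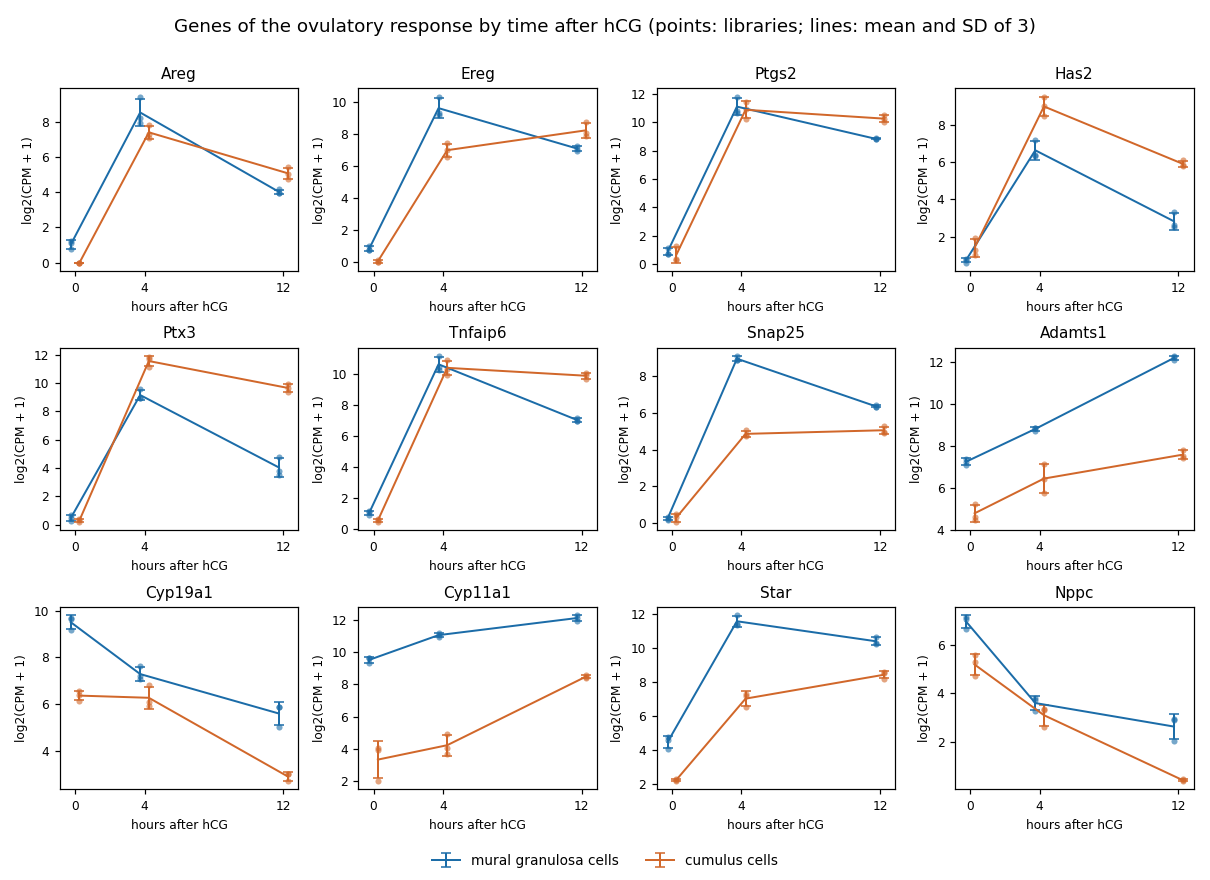
Levels of 12 key genes after hCG. The y axis gives log2(CPM + 1) and the x axis hours after hCG, with 1 point per library for mural and cumulus cells and lines through the mean ± SD of 3 libraries. Ptx3 reaches 581 CPM in mural and 3077 CPM in cumulus cells at 4 h.

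At 12 h after hCG, near the time of ovulation, mural cells were compared with 0 h. Edn2, which encodes the constrictor peptide endothelin 2, rose from 0.216 ± 0.127 to 337 ± 39.4 CPM (10.61 ± 0.51). The protease gene Adamts1 went from 151 ± 16.7 to 4715 ± 312 CPM (4.96 ± 0.3). Spp1, which encodes the secreted protein osteopontin, went from 1.6 ± 0.627 to 3789 ± 378 CPM (11.21 ± 0.32). Cyp11a1, the cholesterol side-chain cleavage enzyme of progesterone synthesis, rose from 735 ± 88.8 to 4425 ± 536 CPM (2.59 ± 0.4), while Cyp19a1 fell from 734 ± 145 to 49.5 ± 15.4 CPM (-3.89 ± 0.28). Still above 0 h were the growth factors Areg (3.83 ± 0.39), Ereg (7.39 ± 0.42) and Btc (4.8 ± 0.25), with Ptgs2 (9.1 ± 0.55) and Snap25 (8.65 ± 0.29). The same held for Has2, Ptx3, Tnfaip6, Star, Il6, Runx1 and Cebpb, at 1.83 to 7.94 (SE 0.13 to 0.57). Below 0 h were Fshr (-3.13 ± 0.2), Inhba (-3.66 ± 0.29), Inhbb (-4.19 ± 0.27), Npr2 (-2 ± 0.17) and Nppc (-4.53 ± 0.31). Each of these had an adjusted p of at most 4.48e-05. Lhcgr (-0.28 ± 0.39, adjusted p = 0.628) was not called. The largest falls included Adam3 (-8.73 ± 0.8) and the BMP antagonist gene Grem1 (-5 ± 0.24), and Sprr2g rose at least 1630-fold from 0 counts.

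Of the 34 lists, 18 were called, 13 up and 5 down, and 7 held with an estimated correlation. In EGF-like ligands and ERK feedback 10 of 14 rose and 1 fell (median 2.7, adjusted p = 1.99e-09, adjusted p = 0.0317 with an estimated correlation). Of ovulatory regulators 14 of 17 rose and 2 fell (median 2.93, adjusted p = 3.52e-16, adjusted p = 0.0317 with an estimated correlation). Among estradiol and follicular-phase genes 12 of 14 fell (13 adjusted over the list alone, median -2.34, adjusted p = 2.02e-16, adjusted p = 0.0453 with an estimated correlation). Of matrix proteases and inhibitors 15 of 20 rose and 2 fell (16 and 2 adjusted over the list alone, median 1.5, adjusted p = 7.75e-13, adjusted p = 0.0317 with an estimated correlation), with Mmp19 (7 ± 0.36) and Timp1 (6.99 ± 0.16). Among cytokines 14 of 21 rose (median 1.69, adjusted p = 1.57e-08, adjusted p = 0.0103 with an estimated correlation), with Lif (5.41 ± 0.32). In hypoxia and angiogenic signals 13 of 18 rose and 2 fell (median 1.63, adjusted p = 4.12e-06, adjusted p = 0.0453 with an estimated correlation), with Adm (7.43 ± 0.5) and Ndrg1 (4.86 ± 0.35). In regulated exocytosis 6 of 14 rose and 1 fell (median 0.39, adjusted p = 0.00289, adjusted p = 0.0466 with an estimated correlation). The next lists did not hold. In cholesterol synthesis and uptake 20 of 23 rose (median 1.2, adjusted p = 7.67e-13, adjusted p = 0.0808 with an estimated correlation), with Dhcr7 (2.4 ± 0.14) and Idi1 (1.98 ± 0.18). In progesterone synthesis 10 of 14 rose and 2 fell (median 1.18, adjusted p = 0.000139, adjusted p = 0.218 with an estimated correlation). Of S phase genes 18 of 19 fell and 1 rose (median -1.05, adjusted p = 2.89e-08, adjusted p = 0.136 with an estimated correlation), with Mcm3 (-1.75 ± 0.15) and Cdc6 (-1.67 ± 0.22). Among granulosa identity genes 8 of 10 fell (9 adjusted over the list alone, median -2.34, adjusted p = 3.33e-10, adjusted p = 0.052 with an estimated correlation). Of theca markers 5 of 8 fell (6 adjusted over the list alone, median -1.4, adjusted p = 0.00965, adjusted p = 0.0808 with an estimated correlation). Immediate early factors, the expansion matrix, glycolysis and brakes, with Hk2 (2.33 ± 0.17) and Cdkn1a (4.43 ± 0.26), were called up and mitosis down (adjusted p = 4.81e-09 to 0.00517, adjusted p = 0.131 to 0.545 with an estimated correlation). Prostaglandin genes were called up (adjusted p = 0.00894, adjusted p = 0.129 with an estimated correlation) at a median of 0.09, which turned negative with library totals (-0.09) and without replicate 3 of 12 h (-0.03). All 6 erythroid markers were higher (median 2.29), a list not called at adjusted p = 0.0511 but called in 4 alternatives (0.0218 to 0.0456). So were the 3 neutrophil markers (median 4.01, or 3.68 with genes at their bound), not called at 0.262. In total 8108 genes were called, 4310 higher and 3798 lower (3981 and 3294 not oocyte-linked). Library totals moved the median of all genes from -0.05 to -0.22 and the share higher from 53.2 to 39.9%.

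Between 4 and 12 h some genes of mural cells fell and others rose. Pgr fell from 1974 ± 570 to 4.47 ± 2.36 CPM (-8.79 ± 0.4) and Sult1e1 from 1465 ± 412 to 5.69 ± 0.817 CPM (-8.01 ± 0.28). The growth factors Areg (-4.73 ± 0.36), Ereg (-2.62 ± 0.32) and Btc (-4.62 ± 0.23) and the matrix genes Has2 (-4.02 ± 0.36) and Ptx3 (-5.13 ± 0.35) fell. So did Tnfaip6, Ptgs2, Snap25 and Star, at -1.19 to -3.66 (SE 0.19 to 0.39). Edn2 rose from 3.87 ± 1.58 to 337 ± 39.4 CPM (6.44 ± 0.4), with Adamts1 (3.39 ± 0.28) and Il6 (2.87 ± 0.41). Follicular genes fell, with Inhba (-3.5 ± 0.29), Cyp19a1 (-1.67 ± 0.25) and Fshr (-0.95 ± 0.19). Adjusted p was at most 0.000777. The largest changes took in rises of Ldhd (7.02 ± 0.56) and Apln (5.47 ± 0.28) and falls of the neuropeptide genes Npy (-8.09 ± 0.68) and Tac1 (-6.35 ± 0.38).

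There were 14 called lists, 6 up and 8 down, and none held with an estimated correlation, where 6 of the 34 had an unadjusted p under 0.05. Of cholesterol genes 18 of 23 rose (19 adjusted over the list alone, median 1, adjusted p = 3.89e-10, adjusted p = 0.255 with an estimated correlation), and in glycolysis 12 of 17 rose and 1 fell (median 0.86, adjusted p = 1.44e-06, adjusted p = 0.358 with an estimated correlation). Of EGF-like ligands 6 of 14 fell and 2 rose (7 and 2 adjusted over the list alone, median -0.55, adjusted p = 0.000417, adjusted p = 0.255 with an estimated correlation). Among estradiol genes 8 of 14 fell (median -1.01, adjusted p = 3.19e-06, adjusted p = 0.281 with an estimated correlation). Of S phase genes 15 of 19 fell and 1 rose (median -0.59, adjusted p = 0.000182, adjusted p = 0.375 with an estimated correlation). In Notch signalling 6 of 12 fell and 1 rose (median -0.72, adjusted p = 0.00315, adjusted p = 0.255 with an estimated correlation). Mitochondrially encoded transcripts fell in 13 of 13 (median -0.76, adjusted p = 0.000913, adjusted p = 0.603 with an estimated correlation), beside shares of 5.24 to 7.57% at 4 h and 3.54 to 4.15% at 12 h. Matrix proteases and hypoxia signals were also called up, and gap junctions and granulosa identity down (adjusted p = 0.000913 to 0.0256, adjusted p = 0.255 to 0.404 with an estimated correlation). Clock genes and cytokines up and the expansion matrix down were called too (adjusted p = 0.00878 to 0.0339, adjusted p = 0.255 to 0.603 with an estimated correlation). These 3 calls ended without oocyte-linked genes (0.131, 0.0552 and 0.0509), with medians of 0.67, 0.38 and -0.67 instead of 0.65, 0.35 and -0.69. The clock call ended also with library totals (0.0554) and the cytokine call without replicate 1 of 4 h (0.0537). In total 6873 genes were called, 3659 higher and 3214 lower (3238 and 2946 not oocyte-linked). Library totals put the median of all genes at 0.16 instead of 0.01 and the share higher at 66.8 instead of 53.2%.

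**Figure D3:**
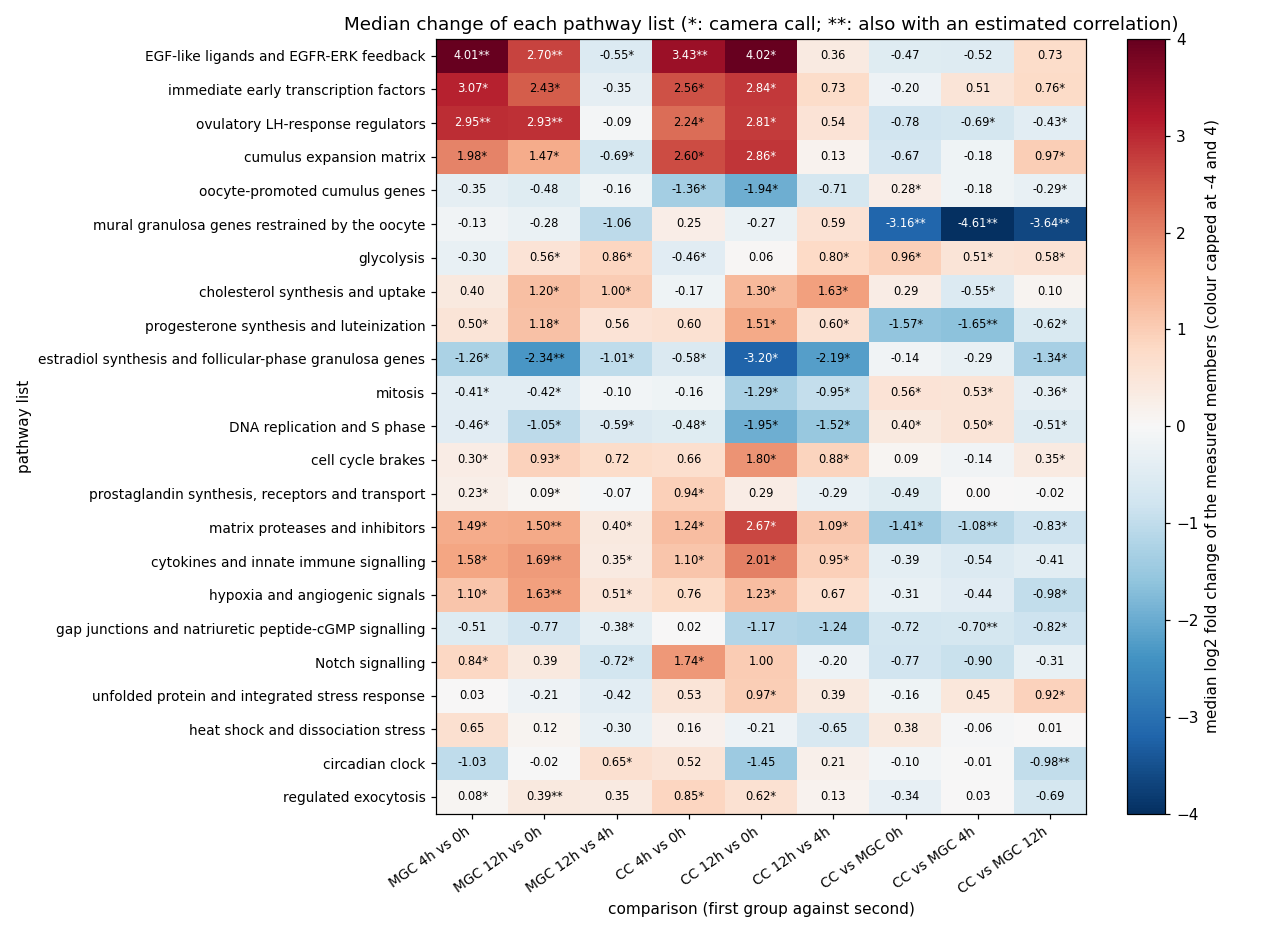
Median log2 change of the 23 pathway lists in 9 comparisons. Each line is a list and each column a comparison, colour gives the median from -4 to 4 (values beyond are drawn at the end of the scale), * marks a list called by camera and ** one called also with an estimated correlation. EGF-like ligands stand at 4.01 in mural and 3.43 in cumulus cells for 4 against 0 h.

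The same early question was asked of the cumulus cells, which surround the oocyte in a matrix they make after the LH signal. Genes of that expansion matrix rose. Ptx3 went from 0.237 ± 0.0883 to 3077 ± 716 CPM (13.6 ± 0.52), Has2 from 1.78 ± 0.949 to 527 ± 189 CPM (8.24 ± 0.43), and Tnfaip6 from 0.471 ± 0.085 to 1411 ± 469 CPM (11.53 ± 0.37). Ptgs2 reached 2001 ± 768 CPM (11.76 ± 0.61). Areg, which had no counts at 0 h, stood at 171 ± 45.7 CPM, at least 7300-fold higher, with Btc (8.14 ± 0.28) beside it. Ereg (11.88 ± 0.6) had counts at 0 h in replicate 1 alone (0.11 CPM). Its folds over 0 h are uncertain. Pgr rose to 70.3 ± 22.4 CPM (8.95 ± 0.48), with Star (5.16 ± 0.26) and Snap25 (6.82 ± 0.28). Il6, Runx1, Cebpb and Adamts1 rose too, at 1.43 to 5.27 (SE 0.13 to 0.6). Falls were seen in Fshr (-2.84 ± 0.2), Npr2 (-1.77 ± 0.17), Nppc (-2.22 ± 0.28) and Ccnd2 (-0.99 ± 0.17). For the genes named so far adjusted p was at most 0.000149. Not called were Cyp19a1 (-0.05 ± 0.25, adjusted p = 0.878) and Cyp11a1 (0.79 ± 0.4, 0.109). The largest rises took in Nts (0 counts at 0 h, at least 10800-fold) and the opioid peptide gene Pdyn (at least 1630-fold). The largest falls took in Jakmip3 (-6.58 ± 0.35) and Cacna1a (-4.64 ± 0.18).

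Here 15 of the 34 lists were called, 9 up and 6 down, and EGF-like ligands alone held with an estimated correlation. Of those ligand and feedback genes 10 of 14 rose and 2 fell (11 and 2 adjusted over the list alone, median 3.43, adjusted p = 7.57e-13, adjusted p = 0.0449 with an estimated correlation). In the expansion matrix 14 of 17 rose and 2 fell (median 2.6, adjusted p = 7.57e-13, adjusted p = 0.148 with an estimated correlation). Of ovulatory regulators 13 of 17 rose and 2 fell (median 2.24, adjusted p = 3.75e-12, adjusted p = 0.148 with an estimated correlation), with Runx2 (6.89 ± 0.33). Among immediate early factors 10 of 18 rose (11 adjusted over the list alone, median 2.56, adjusted p = 4.34e-08, adjusted p = 0.29 with an estimated correlation). Of matrix proteases 15 of 20 rose and 2 fell (15 and 3 adjusted over the list alone, median 1.24, adjusted p = 0.000154, adjusted p = 0.236 with an estimated correlation). In Notch signalling 9 of 12 rose and 2 fell (median 1.74, adjusted p = 0.0125, adjusted p = 0.222 with an estimated correlation). Of the cumulus genes promoted by the oocyte 6 of 8 fell (median -1.36, adjusted p = 6.94e-05, adjusted p = 0.236 with an estimated correlation), with Slc38a3 (-2.8 ± 0.3). Among estradiol genes 7 of 14 fell and 2 rose (median -0.58, adjusted p = 0.00218, adjusted p = 0.599 with an estimated correlation). Of granulosa identity genes 5 of 10 fell and 1 rose (median -1.1, adjusted p = 0.000527, adjusted p = 0.309 with an estimated correlation). Mitochondrially encoded transcripts fell in 13 of 13 (median -0.77, adjusted p = 0.0089, adjusted p = 0.77 with an estimated correlation). Cytokines and exocytosis were called up (adjusted p = 0.0089 and 0.0109, adjusted p = 0.148 and 0.148 with an estimated correlation).

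Prostaglandin genes up and glycolysis and S phase down were called too (adjusted p = 0.0213 to 0.0263, adjusted p = 0.288 to 0.77 with an estimated correlation). The prostaglandin call ended without replicate 2 of 4 h (0.0593), the glycolysis call without replicate 1 of 0 h (0.0683) or replicate 3 of 4 h (0.158), and the S phase call without replicate 1 of 0 h (0.051) or of 4 h (0.0513). Glycolysis and S phase lost their calls also with the oocyte sum as a covariate (0.111 and 0.0753, medians from -0.46 and -0.48 to -0.22 and -0.41) and without oocyte-linked genes (0.056 and 0.1, medians -0.43 for each). The 15 oocyte markers had a median of 1.31. Called were 9532 genes, 4987 higher and 4545 lower (3945 and 4373 not oocyte-linked), 9580 without the 2 libraries that stood apart and 5509 with only the libraries compared in the fit. Library totals moved the median of all genes from 0.13 to -0.01 and the share higher from 52.3 to 41%.

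At 12 h cumulus cells differed from 0 h in 12796 genes, and oocyte RNA was nearly gone from their libraries. These libraries' oocyte sums lie below all others, so covariate fits extrapolate to them, and a call so ended need not be oocyte RNA. Whether the cells of 12 h were collected as those of 0 and 4 h is not given, so time and collection are not separated. Spp1 rose from 1.6 ± 0.629 to 14180 ± 437 CPM (13.09 ± 0.34), Cyp11a1 from 11.1 ± 7.06 to 356 ± 18.9 CPM (5 ± 0.45) and Star from 3.72 ± 0.197 to 348 ± 48.7 CPM (6.54 ± 0.28). Matrix and growth factor genes were above 0 h, with Ptx3 (11.69 ± 0.5), Tnfaip6 (10.97 ± 0.36), Has2 (5.09 ± 0.39) and Ereg (13.14 ± 0.6). Areg was at least 1440-fold higher than its 0 counts at 0 h. Other rises were Btc, Ptgs2, Snap25, Il6, Runx1 and Cebpb, at 1.8 to 11.07 (SE 0.13 to 0.59). Fshr fell from 298 ± 15.4 to 5.33 ± 1.68 CPM (-5.8 ± 0.23) and Inhbb from 8034 ± 1930 to 110 ± 11.9 CPM (-6.18 ± 0.3). So did Nppc (-6.73 ± 0.39), Cyp19a1 (-3.63 ± 0.28), the anti-Mullerian hormone gene Amh (-3.9 ± 0.46) and the cyclin gene Ccnd2 (-3.36 ± 0.19). Adjusted p was at most 9.41e-07. The rises of Adamts1 (2.81 ± 0.27, adjusted p = 8.76e-08) and Pgr (2.56 ± 0.63, 0.00183) lost their calls with the oocyte sum as a covariate (0.81 and 1.94), that of Pgr also with limma-voom (2.52). The largest rises included Nts (at least 9090-fold over 0 counts) and Krt23 (at least 5110-fold). Outside oocyte-linked genes the largest falls included Cnnm1 (-9.45 ± 0.42), Mycl (-8.41 ± 0.39) and the hedgehog ligand gene Ihh (-7.53 ± 0.38).

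Oocyte markers fell in 15 of 15 (median -7.42, or -7.35 with genes at their bound, adjusted p = 6.36e-06, adjusted p = 0.361 with an estimated correlation). With their own sum as a covariate that call was bound to end (0.43, median -0.49). Zp1, Eif4e1b, Fbxw21 and Tuba3a had no counts at 12 h and were at least 2570, 3300, 1230 and 1020-fold lower. Mitochondrially encoded transcripts fell in 13 of 13 (median -1.66, adjusted p = 9.08e-06, adjusted p = 0.357 with an estimated correlation), beside shares of 8.49 to 12.8% at 0 h and 2.52 to 2.98% at 12 h. Of S phase genes 19 of 19 fell (median -1.95, adjusted p = 4.56e-15, adjusted p = 0.103 with an estimated correlation), with Cdc6 (-3.43 ± 0.24) and Mcm3 (-2.61 ± 0.16), and 2 of these genes were oocyte-linked. Among mitosis genes 20 of 20 fell (median -1.29, adjusted p = 9.62e-08, adjusted p = 0.155 with an estimated correlation), and 9 of them were oocyte-linked. Of estradiol genes 13 of 14 fell and 1 rose (median -3.2, adjusted p = 6.59e-10, adjusted p = 0.155 with an estimated correlation). Among granulosa identity genes 10 of 10 fell (median -2.79, adjusted p = 9.62e-08, adjusted p = 0.155 with an estimated correlation). Of genes promoted by the oocyte 6 of 8 fell (median -1.94, adjusted p = 7.50e-05, adjusted p = 0.225 with an estimated correlation).

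In EGF-like ligands and ERK feedback 11 of 14 rose and 3 fell (median 4.02, adjusted p = 2.67e-07, adjusted p = 0.108 with an estimated correlation). Of immediate early factors 14 of 18 rose (median 2.84, adjusted p = 9.62e-08, adjusted p = 0.225 with an estimated correlation). In the expansion matrix 14 of 17 rose and 2 fell (median 2.86, adjusted p = 4.24e-08, adjusted p = 0.188 with an estimated correlation). Of matrix proteases 15 of 20 rose and 2 fell (median 2.67, adjusted p = 1.05e-10, adjusted p = 0.0735 with an estimated correlation). Ovulatory regulators, cytokines and exocytosis were called up as well (adjusted p = 1.60e-07 to 0.0353, adjusted p = 0.06 to 0.155 with an estimated correlation), the last not with the replicate block (0.0599). In cholesterol synthesis 20 of 23 rose and in progesterone synthesis 10 of 14. These lists, cell cycle brakes, hypoxia signals and the unfolded protein response were called up (adjusted p = 1.03e-05 to 0.0419, adjusted p = 0.205 to 0.686 with an estimated correlation), and with the oocyte sum as a covariate those 5 calls ended (0.706, 0.287, 0.207, 0.659 and 0.659). Their medians went from 1.3, 1.51, 1.8, 1.23 and 0.97 to 0.18, 0.62, 1.25, 0.85 and -0.1. The hypoxia and unfolded protein calls ended also without oocyte-linked genes (0.137 and 0.134, medians 0.69 and 0.76), the former without replicate 2 of 0 h (0.05) and the latter without replicate 3 (0.0554). Camera called 19 lists, 12 up and 7 down, and none of them held with an estimated correlation, where 9 of 34 had an unadjusted p under 0.05. Of the 12796 called genes 6226 were higher and 6570 lower, and 9976 were not oocyte-linked, 5868 higher and 4108 lower. The count was 13792 without the 2 libraries that stood apart and 6701 with the oocyte sum as a covariate. Library totals moved the median of all genes from -0.09 to -0.34 and the share higher from 48.7 to 38.1%.

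From 4 to 12 h some genes of cumulus cells fell and others rose. Pgr fell from 70.3 ± 22.4 to 0.837 ± 0.249 CPM (-6.39 ± 0.4), Has2 from 527 ± 189 to 59.5 ± 7 CPM (-3.15 ± 0.33) and Cyp19a1 from 79.3 ± 27.6 to 6.61 ± 0.916 CPM (-3.58 ± 0.28). So did Btc, Fshr, Inhba, Ccnd2, Nppc and Amh, at -1.7 to -4.51 (SE 0.18 to 0.45) (adjusted p at most 5.03e-06). The largest rises included Npy4r (no counts at 4 h, at least 1110-fold), Tgm2 (8.39 ± 0.35), Vsir (7.95 ± 0.59) and the histidine decarboxylase gene Hdc (6.92 ± 0.26). Outside oocyte-linked genes the largest falls took in Esm1 (-6.64 ± 0.71), Ihh (-5.83 ± 0.36) and Ass1 (-5.68 ± 0.22). The calls of Areg (-2.36 ± 0.33), Ptx3 (-1.91 ± 0.3), Edn2 (4.2 ± 0.52), Star (1.39 ± 0.22) and Cyp11a1 (4.21 ± 0.44) ended with the oocyte sum as a covariate (-3.94, -1.28, 5.24, 1.03 and 2.95). Those of Ereg (1.26 ± 0.3), Adamts1 (1.05 ± 0.26) and Il6 (1.65 ± 0.4) ended too, with values that turned negative (-0.59, -1.26 and -0.19).

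Camera called 12 lists, 6 up and 6 down, and none held with an estimated correlation, where 5 of 34 had an unadjusted p under 0.05. Of matrix proteases 13 of 20 rose and 3 fell (median 1.09, adjusted p = 1.84e-07, adjusted p = 0.201 with an estimated correlation). Of S phase genes 19 of 19 fell (median -1.52, adjusted p = 3.01e-15, adjusted p = 0.201 with an estimated correlation). Among mitosis genes 19 of 20 fell (median -0.95, adjusted p = 5.98e-07, adjusted p = 0.31 with an estimated correlation). Of estradiol genes 13 of 14 fell (median -2.19, adjusted p = 6.86e-08, adjusted p = 0.343 with an estimated correlation). Among granulosa identity genes 8 of 10 fell and 1 rose (median -1.37, adjusted p = 0.000471, adjusted p = 0.434 with an estimated correlation). Mitochondrially encoded transcripts fell in 13 of 13 (median -0.92, adjusted p = 0.00349, adjusted p = 0.767 with an estimated correlation), and oocyte markers in 15 of 15 (median -8.68, or -8.61 with genes at their bound, adjusted p = 3.82e-09, adjusted p = 0.432 with an estimated correlation). In cholesterol synthesis 22 of 23 rose and in glycolysis 13 of 17. These lists, progesterone synthesis, brakes and cytokines were called up (adjusted p = 3.47e-13 to 0.00756, adjusted p = 0.201 to 0.711 with an estimated correlation). Those 5 calls and that of the oocyte markers ended with the oocyte sum as a covariate (0.293, 0.123, 0.661, 0.542, 0.195 and 0.327). Their medians went from 1.63, 0.8, 0.6, 0.88, 0.95 and -8.68 to 0.2, -0.75, -0.41, 0.36, 0.79 and -0.43. In total 12065 genes were called, 5823 higher and 6242 lower, 3051 of the lower ones oocyte-linked. Outside oocyte-linked genes 8855 were called, 5664 higher and 3191 lower. The count was 4288 with the oocyte sum as a covariate and 12204 without the 2 libraries that stood apart. With library totals the median of all genes went from -0.04 to -0.15.

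Cumulus against mural cells at 0 h shows how the cell types differ before hCG. Lhcgr stood at 662 ± 83.6 CPM in mural and 8.52 ± 5.7 CPM in cumulus cells (-6.29 ± 0.5), and Cyp11a1 at 735 ± 88.8 and 11.1 ± 7.06 CPM (-6.04 ± 0.48). Cyp19a1 stood at 734 ± 145 and 82.2 ± 11.8 CPM (-3.16 ± 0.27). Also lower in cumulus cells were Star (-2.53 ± 0.24), Nppc (-1.78 ± 0.27), Pgr (-3.88 ± 0.54), Adamts1 (-2.47 ± 0.27) and Inhba (-1.27 ± 0.27). Areg, with no counts there, was at least 46.3-fold lower. Higher were Npr2 (0.6 ± 0.16), the receptor of the natriuretic peptide, Runx1 (1.11 ± 0.19) and Cebpb (0.86 ± 0.13), and adjusted p for these genes was at most 0.0063. Fshr (0.19 ± 0.19, adjusted p = 0.41), Amh (0.02 ± 0.4, 0.972) and Ccnd2 (0.03 ± 0.17, 0.914) were not called. The largest differences upward included Rbfox1 (3.94 ± 0.12), Kctd14 (3.54 ± 0.4) and Otof (3.09 ± 0.23). Downward they included the collagen genes Col3a1 (-7.9 ± 0.52) and Col1a1 (-6.85 ± 0.34) and the theca gene Cyp17a1 (-7.6 ± 0.47).

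Of the 34 lists, 15 were called, 6 up and 9 down, and 3 held with an estimated correlation. Of the mural genes restrained by the oocyte 7 of 7 were lower (median -3.16, adjusted p = 5.07e-11, adjusted p = 0.0256 with an estimated correlation), with Cd34 (-5.62 ± 0.41). Among stromal markers 7 of 8 were lower (median -5.63, adjusted p = 5.32e-08, adjusted p = 0.046 with an estimated correlation). Of theca markers 7 of 8 were lower and 1 higher (median -2.37, adjusted p = 0.000188, adjusted p = 0.046 with an estimated correlation). Of progesterone genes 12 of 14 were lower (median -1.57, adjusted p = 1.03e-09, adjusted p = 0.0796 with an estimated correlation), with Prlr (-4.2 ± 0.25) and Hsd3b1 (-3.85 ± 0.2). Among matrix proteases 14 of 20 were lower and 1 higher (15 and 1 adjusted over the list alone, median -1.41, adjusted p = 2.29e-07, adjusted p = 0.0796 with an estimated correlation). Smooth muscle and epithelial markers were called down (adjusted p = 0.000247 and 0.00941, adjusted p = 0.211 and 0.163 with an estimated correlation). In glycolysis 13 of 17 were higher and 3 lower (median 0.96, adjusted p = 2.93e-05, adjusted p = 0.494 with an estimated correlation), with Ldha (1.61 ± 0.2). Mitochondrially encoded transcripts were higher in 13 of 13 (median 1.11, adjusted p = 1.97e-05, adjusted p = 0.494 with an estimated correlation). Of oocyte markers 14 of 15 were higher (median 2.15, adjusted p = 0.00218, adjusted p = 0.582 with an estimated correlation). S phase and mitosis were called up (adjusted p = 0.000694 and 0.00133, adjusted p = 0.494 and 0.494 with an estimated correlation).

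Genes promoted by the oocyte up, and granulosa identity and erythroid markers down, were called too (adjusted p = 0.0176 to 0.0348, adjusted p = 0.502 to 0.571 with an estimated correlation). The first call ended without replicate 1 of the cumulus cells (0.0704), and the erythroid call without their replicate 1, 2 or 3 (0.066, 0.0738 and 0.0799) and with library totals (0.077). Without oocyte-linked genes the erythroid and identity calls ended (0.176 and 0.0743, medians from -3.83 and -0.82 to -3.72 and -0.7). With the oocyte sum as a covariate those of identity, oocyte and erythroid markers did (0.255, 0.522 and 0.17, medians -0.55, 0.07 and -3.83). For the oocyte markers, whose own sum the covariate is, that end was fixed. Called were 9333 genes, 4295 higher and 5038 lower (2860 and 4845 not oocyte-linked), and 11174 without the 2 libraries that stood apart.

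**Figure D4:**
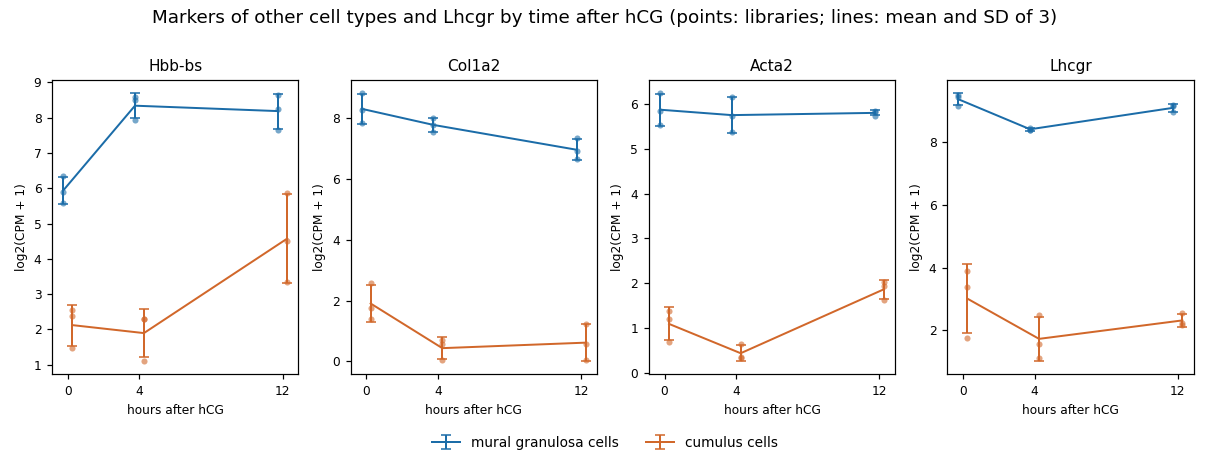
Transcripts of other cells and of the LH receptor per library. The y axis gives log2(CPM + 1) of Hbb-bs (red blood cells), Col1a2 (stroma), Acta2 (smooth muscle) and Lhcgr, the x axis the 6 groups, with 1 point per library and n = 3 per group. Mean Col1a2 is 330 CPM in mural and 2.97 CPM in cumulus cells at 0 h.

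At 4 h the cell types differed in levels, for some genes already at 0 h. Cumulus cells had more Has2 (2.36 ± 0.32) and Ptx3 (2.4 ± 0.31). Mural cells had more Snap25 (487 ± 45.3 against 27.9 ± 3.75 CPM, -4.12 ± 0.21) and Pgr (1974 ± 570 against 70.3 ± 22.4 CPM, -4.81 ± 0.33). Star stood at 3113 ± 711 CPM in mural and 133 ± 35.6 CPM in cumulus cells (-4.55 ± 0.25). Lower in cumulus cells were also Lhcgr (-6.99 ± 0.53), Cyp11a1 (-6.78 ± 0.49), Ereg (-2.69 ± 0.32) and Adamts1 (-2.28 ± 0.27), with adjusted p at most 1.47e-05. Ptgs2 (-0.24 ± 0.37, adjusted p = 0.608) and Il6 (-0.48 ± 0.4, 0.328) were not called. The calls of Btc (-1.02 ± 0.2) and Areg (-1.25 ± 0.31) ended with the oocyte sum as a covariate (-0.62 and -0.59), that of Areg also without replicate 3 of the cumulus cells (-1.04). Outside oocyte-linked genes the largest rises included Krt76 (4.76 ± 0.5), Il23a (4.23 ± 0.36) and Pdyn (3.26 ± 0.39). The largest falls included Npr1 (-7.73 ± 0.45), Col1a2 (-9.29 ± 0.69) and Cyp17a1, at least 1030-fold lower than in mural cells.

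Among the 34 lists 16 were called, 4 up and 12 down, and 7 held with an estimated correlation. Of mural genes restrained by the oocyte 6 of 7 were lower (median -4.61, adjusted p = 2.10e-10, adjusted p = 0.0499 with an estimated correlation). Among progesterone genes 13 of 14 were lower (median -1.65, adjusted p = 5.53e-12, adjusted p = 0.0499 with an estimated correlation), with Prlr (-4.35 ± 0.25). Of matrix proteases 15 of 20 were lower and 2 higher (median -1.08, adjusted p = 2.14e-08, adjusted p = 0.0499 with an estimated correlation). In gap junctions and natriuretic peptide signalling 6 of 12 were lower and 3 higher (median -0.7, adjusted p = 0.00496, adjusted p = 0.0499 with an estimated correlation), with Npr3 (-3.32 ± 0.29) and Gucy1a1 (-2.78 ± 0.25). Theca, stromal and epithelial markers, the last of the 7, had medians of -1.46, -5.96 and -3.38 (adjusted p = 3.51e-08 to 0.00296, adjusted p = 0.0499 to 0.0499 with an estimated correlation). Of erythroid markers 6 of 6 were lower (median -6.42, adjusted p = 3.24e-05, adjusted p = 0.206 with an estimated correlation), with Hbb-bs (-6.77 ± 0.64). Of oocyte markers 15 of 15 were higher (median 4.09, adjusted p = 9.09e-06, adjusted p = 0.429 with an estimated correlation). Mitosis and S phase were called up and smooth muscle markers down (adjusted p = 0.000855 to 0.00231, adjusted p = 0.261 to 0.446 with an estimated correlation).

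Of ovulatory regulators 11 of 17 were lower and of cholesterol genes 13 of 23. In glycolysis 11 of 17 were higher. These lists and granulosa identity, the last lower, were called (adjusted p = 7.15e-05 to 0.0363, adjusted p = 0.261 to 0.526 with an estimated correlation). The oocyte sum as a covariate ended the calls of ovulatory, cholesterol, identity and oocyte genes (0.058, 0.775, 0.544 and 0.535). Their medians went from -0.69, -0.55, -0.48 and 4.09 to -0.36, 0.04, 0.04 and 0.12. At 4 h the sum did not overlap between cell types (cumulus 1318 to 8087, mural 180.9 to 274.7 CPM). A call so ended need not be oocyte RNA. Without oocyte-linked genes the cholesterol and identity calls ended (0.0626 and 0.121, medians -0.37 and -0.29). The identity call ended also without replicate 3 of cumulus (0.145) or replicate 2 of mural cells (0.0724), and the glycolysis call without replicate 2 of cumulus cells (0.07). Called were 10876 genes, 5501 higher and 5375 lower, or 7891 outside oocyte-linked genes, 2562 higher and 5329 lower. The count was 5662 with the covariate and 10875 without the 2 libraries that stood apart. With library totals the median of all genes was 0.12 instead of 0.

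At 12 h some matrix genes were higher in cumulus than in mural cells. Ptx3 stood at 819 ± 150 against 16.7 ± 8.5 CPM (5.62 ± 0.36) and Tnfaip6 at 962 ± 125 against 131 ± 11.7 CPM (2.88 ± 0.24), with Has2 (3.23 ± 0.35). Mural cells had more Adamts1 (4715 ± 312 against 192 ± 29.2 CPM, -4.61 ± 0.29) and Edn2 (337 ± 39.4 against 3.68 ± 0.809 CPM, -6.52 ± 0.4). They also had more Lhcgr (-7.09 ± 0.53), Cyp11a1 (-3.64 ± 0.42), Fshr (-2.47 ± 0.21) and Amh (-4.01 ± 0.46). Star, Cyp19a1, Nppc, Ccnd2, Snap25, Pgr and Il6 were lower in cumulus cells too, at -1.32 to -3.98 (SE 0.18 to 0.39). Adjusted p was at most 0.00194, and Runx1 (0.12 ± 0.19, adjusted p = 0.64) was not called. The calls of Ereg (1.19 ± 0.3) and Ptgs2 (1.44 ± 0.37) ended with the oocyte sum as a covariate (0.15 and 0.05). The largest differences upward included the retinaldehyde dehydrogenase gene Aldh1a3 (5.69 ± 0.29), Pdcd1 (5.38 ± 0.28) and Krt23 (5.37 ± 0.32). Downward they included Col1a2 (-7.61 ± 0.63) and Cd34 (-6.9 ± 0.41).

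Of the 34 lists, 22 were called, 5 up and 17 down, and 2 held with an estimated correlation. Of mural genes restrained by the oocyte 7 of 7 were lower (median -3.64, adjusted p = 3.74e-09, adjusted p = 0.0424 with an estimated correlation). Among circadian clock genes 9 of 16 were lower and 1 higher (median -0.98, adjusted p = 0.000347, adjusted p = 0.0424 with an estimated correlation), with Per2 (-3.66 ± 0.21), a call that ended with the oocyte sum as a covariate (0.0681, median -0.48). Of estradiol genes 9 of 14 were lower and 3 higher (median -1.34, adjusted p = 0.00315, adjusted p = 0.42 with an estimated correlation). Among S phase genes 14 of 19 were lower and 1 higher (16 and 1 adjusted over the list alone, median -0.51, adjusted p = 0.00147, adjusted p = 0.393 with an estimated correlation). Of ovulatory regulators 8 of 17 were lower and 7 higher (median -0.43, adjusted p = 0.0225, adjusted p = 0.42 with an estimated correlation), a list not called with the replicate block (0.0723). Progesterone, protease, hypoxia and granulosa identity genes were called down (adjusted p = 5.39e-05 to 0.0293, adjusted p = 0.284 to 0.393 with an estimated correlation). So were stromal, smooth muscle and erythroid markers, with medians of -5.18, -4.29 and -3.29 (adjusted p = 1.19e-05 to 0.000606, adjusted p = 0.0623 to 0.245 with an estimated correlation). Epithelial markers, and oocyte markers in 15 of 15 (median -4.36, or -4.3 with genes at their bound), were called down (adjusted p = 0.00183 and 1.14e-06, adjusted p = 0.0623 and 0.393 with an estimated correlation), but not with the covariate (0.0681 and 0.822, medians from -2.2 and -4.36 to -2.06 and 0.07).

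In the unfolded protein response 8 of 12 were higher and in the expansion matrix 10 of 17. These lists, immediate early factors, glycolysis and brakes were called up (adjusted p = 1.19e-05 to 0.0413, adjusted p = 0.34 to 0.563 with an estimated correlation). With the covariate the 5 calls ended (0.331, 0.739, 0.142, 0.3 and 0.822), and the medians went from 0.92, 0.97, 0.76, 0.58 and 0.35 to 0.11, -0.12, -1.3, -0.19 and -0.02. Mitosis, gap junction genes and genes promoted by the oocyte were called down (adjusted p = 0.0326 to 0.0413, adjusted p = 0.245 to 0.458 with an estimated correlation). The mitosis and gap junction calls ended with the covariate (0.0521 and 0.105, medians from -0.36 and -0.82 to -0.32 and -0.84). Without oocyte-linked genes the last call, that of immediate early factors and that of gap junctions ended (0.0694, 0.132 and 0.0609, medians from -0.29, 0.76 and -0.82 to -0.36, 0.7 and -0.59). Without replicate 3 of mural cells the calls of immediate early factors and brakes ended (0.0634 for each). The mitosis call ended without replicate 1 of mural (0.0506) or replicate 2 (0.0555) or 3 (0.0504) of cumulus cells, and the gap junction call without replicate 2 of cumulus cells (0.0555). Called were 7680 genes, 3590 higher and 4090 lower (3364 and 3082 not oocyte-linked), and with a 2-fold minimum 913 higher and 2886 lower. Library totals moved the median of all genes from -0.07 to -0.19 and the share higher from 46.7 to 35.6%. Heat shock genes and markers of endothelial cells, macrophages and neutrophils were called in none of the 11 comparisons in the main fit (lowest adjusted p = 0.176, 0.0683, 0.0631 and 0.124). In alternatives endothelial markers were called down between cell types at each time, and macrophages at 4 and 12 h and for the difference at 4 h.

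The next question is whether the change from 0 to 4 h differed between the cell types, taken as the cumulus change minus the mural change. Snap25 rose less in cumulus than in mural cells (-4.43 ± 0.51), as did Star (-2.01 ± 0.32) and Runx1 (-1.8 ± 0.27). Cyp19a1, which fell in mural cells and was not called in cumulus cells, differed by 2.17 ± 0.35 (adjusted p at most 0.000482). Aldh1a3 went from 2.23 ± 0.269 to 6.08 ± 1.23 CPM in mural and from 0.259 ± 0.126 to 33.2 ± 12.5 CPM in cumulus cells (5.56 ± 0.43). The difference for Ptx3 was 3.07 ± 0.7 (adjusted p = 0.00677). It was not called with limma-voom (2.98), without replicate 3 of the mural cells at 0 h (2.61) or without the 2 libraries that stood apart (3.01). That for Btc was -1.27 ± 0.31 (adjusted p = 0.0112) and was not called with limma-voom or with only the 4 groups' libraries in the fit (-1.26 for each).

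Camera called 6 lists here and none held with an estimated correlation, where 1 of 34 had an unadjusted p under 0.05. The difference was negative for 11 of 23 cholesterol genes (14 adjusted over the list alone, median -0.67, adjusted p = 9.92e-10, adjusted p = 0.723 with an estimated correlation). It was negative in 4 of 8 genes promoted by the oocyte (median -0.79, adjusted p = 0.000582, adjusted p = 0.723 with an estimated correlation) and in 13 of 13 mitochondrially encoded transcripts (median -1.26, adjusted p = 8.57e-11, adjusted p = 0.723 with an estimated correlation). Erythroid markers were called down at a median of -2.69 (adjusted p = 0.00117, adjusted p = 0.723 with an estimated correlation). Ovulatory regulators were called down (adjusted p = 0.0397, adjusted p = 0.833 with an estimated correlation), a call that ended with the covariate (0.351) and without oocyte-linked genes (0.151), where the median went from -0.34 to -0.12 and -0.27. It ended also without cumulus 0 h replicate 1 (0.0833), cumulus 4 h replicate 1 (0.0521) or 3 (0.265), mural 0 h replicate 1 (0.0968) or 3 (0.0522) or mural 4 h replicate 2 (0.0812). Oocyte markers were called up at a median of 1.96 (adjusted p = 0.0158, adjusted p = 0.833 with an estimated correlation), with no such call with library totals (0.135). Under the covariate, their own sum, the end of the call was fixed (0.991, median 0). Nor was there one without cumulus 0 h replicate 1 (0.186), cumulus 4 h replicate 3 (0.494) or mural 0 h replicate 3 (0.156). Called were 2800 genes, 1352 higher and 1448 lower (1013 and 1423 not oocyte-linked), 3616 without the 2 libraries that stood apart, 1564 with only the libraries compared in the fit and 4272 without replicate 2 of cumulus cells at 4 h. Library totals moved the median of all genes from 0.07 to 0.25 and the share higher from 48.3 to 69.3%.

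For the change from 0 to 12 h, 8003 genes differed between the cell types. Ptx3 (6.29 ± 0.73) and Tnfaip6 (4.06 ± 0.43) rose more in cumulus cells, and Adamts1 (-2.15 ± 0.36) and Runx1 (-0.99 ± 0.27) rose more in mural cells. Fshr (-2.67 ± 0.28), Ccnd2 (-1.73 ± 0.25), Npr2 (-1.13 ± 0.23) and Amh (-4.04 ± 0.6) had the more negative change in cumulus cells (adjusted p at most 0.00678). Aldh1a3 stood at 2.38 ± 0.117 CPM in mural and 123 ± 24 CPM in cumulus cells at 12 h, from 2.23 ± 0.269 and 0.259 ± 0.126 CPM (8.8 ± 0.44). Calls of Ereg (5.75 ± 0.9), Btc (1.65 ± 0.32), Cyp11a1 (2.41 ± 0.55) and Inhba (2.23 ± 0.38) ended with the oocyte sum as a covariate (4.23, 0.87, 1.43 and 1.01). The call of Snap25 (-1.63 ± 0.49) ended with limma-voom (-1.24) and without replicate 2 of cumulus cells at 0 h (-0.97).

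Camera called 8 lists and none held with an estimated correlation, where 1 of 34 had an unadjusted p under 0.05. The difference was negative in 16 of 19 S phase genes (17 adjusted over the list alone, median -0.97, adjusted p = 1.98e-07, adjusted p = 0.575 with an estimated correlation) and in 17 of 20 mitosis genes (median -0.82, adjusted p = 5.19e-05, adjusted p = 0.575 with an estimated correlation). It was negative in 6 of 8 genes promoted by the oocyte (median -1.32, adjusted p = 0.000214, adjusted p = 0.575 with an estimated correlation) and in 13 of 13 mitochondrially encoded transcripts (median -1.4, adjusted p = 8.47e-06, adjusted p = 0.628 with an estimated correlation). All 15 oocyte markers had a negative difference (median -6.9, adjusted p = 6.27e-11, adjusted p = 0.575 with an estimated correlation). Positive were 11 of 17 genes of the expansion matrix (median 1.42, adjusted p = 0.000802, adjusted p = 0.663 with an estimated correlation) and 8 of 12 of the unfolded protein response (median 1.24, adjusted p = 0.000246, adjusted p = 0.628 with an estimated correlation). EGF-like ligands were called up at a median of 0.89 (adjusted p = 0.0347, adjusted p = 0.628 with an estimated correlation). These last 3 calls and the oocyte call ended with the oocyte sum as a covariate (0.98, 0.792, 0.245 and 0.478, medians 0.07, 0.35, 0.92 and -0.55). The EGF call ended also without oocyte-linked genes (0.0617, median 1.24) and without cumulus 0 h replicate 3 (0.0506) or cumulus 12 h replicate 1 (0.0503). Of the 8003 genes 4017 were higher and 3986 lower (3885 and 2470 not oocyte-linked), and the count was 4831 with the covariate and 10110 without the 2 libraries that stood apart.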

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

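The tests of explanations below and the library splits were chosen after the results were seen, while the differences were planned. The values below were picked out because the change after hCG differed between the cell types (log2 cumulus minus mural change, by its test). For 0 to 4 h 2800 genes differed. Among 100 drawn splits of the 12 libraries, the real one included, 9 gave as many, the highest other 12598. All 8 others kept the cell types apart at one of the times, so they hold the difference between cell types and say little of chance. For 0 to 12 h 8003 genes differed, the highest other split gave 8545, and 2 of 100 gave as many. In both sets the 79 splits that mixed the cell types at both times gave 0 genes, as the cell-type difference enters their spread. So neither share can judge chance.

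For the pairs of groups 3 against 3 libraries give 10 splits, too few for a share under 0.05. Each time only the real split gave as many genes as reported. The highest other split gave 1327 for cumulus 4 against 0 h, 3 between cell types at 0 h and 0 in the other 7.

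For 0 to 4 h the key genes that differed were Areg at 7.12 (no counts in cumulus cells at 0 h, so set by the prior count), Ptx3 at 3.07, Cyp19a1 at 2.17, Nppc at 1.25, Npr2 at -0.74, Btc at -1.27, Runx1 at -1.8, Star at -2.01 and Snap25 at -4.43. The largest other differences were Aldh1a3 at 5.56, Flnc at 5.46, Lipg at 4.55, Chrna4 at 4.47, Tnfaip3 at -4.53, Rims4 at -4.82, Pthlh at -5.31 and Abcc2 at -5.42. The Areg call ended without cumulus 4 h replicate 3 (7.34) and with limma-voom (5.36). That of Npr2 ended without any 1 library but replicate 2 of the cumulus cells at 4 h (-0.51 to -0.76). That of Nppc ended without any but mural 0 h replicate 3, cumulus 0 h replicate 1 and cumulus 4 h replicate 3 (1.1 to 1.34).

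For 0 to 12 h the key genes were Areg at 9.5, Ptx3 at 6.29, Ereg at 5.75, Tnfaip6 at 4.06, Cyp11a1 at 2.41, Inhba at 2.23, Ptgs2 at 1.97, Has2 at 1.88 and Btc at 1.65. Negative were Runx1 at -0.99, Npr2 at -1.13, Snap25 at -1.63, Ccnd2 at -1.73, Adamts1 at -2.15, Nppc at -2.2, Fshr at -2.67 and Amh at -4.04. The Has2 call ended without replicate 1 of mural cells (1.75), replicate 2 (1.74) or replicate 3 (1.58) of cumulus cells at 0 h. That of Ptgs2 ended without any 1 library but cumulus 0 h replicate 1 and cumulus 12 h replicates 2 and 3 (1.49 to 2.14). The largest others were Aldh1a3 at 8.8, Krt23 at 8.7, Nts at 8.07, Wisp1 at 7.95, Fbxw16 at -10.26, Tuba3a at -12.19, Fbxw21 at -12.85, Eif4e1b at -13.96 and Zp1 at -14.01. In cumulus cells Areg, Krt23 and Nts had no counts and Ereg few at 0 h. At 12 h Zp1, Eif4e1b, Fbxw21 and Tuba3a had none and Fbxw16 1. These fitted values depend on the prior count.

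A first pattern is the 4314 genes at least 2-fold lower in cumulus cells at 12 than at 4 h. Of these 61% followed the oocyte marker sum within groups, against 9.42% of the other 15627 genes, so RNA of the oocyte may account for part of them. The 11 estradiol and follicular-phase genes among them fell with a higher sum (median t -2.26, upper quartile -1.38), which argues against oocyte RNA for these. A change of the cells with time after hCG stays open for them, untested.

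A second pattern is the lower level of all 13 mitochondrially encoded transcripts in cumulus cells at 12 than at 0 h (median -1.66). A median t of -0.43 on the marker sum (upper quartile -0.32) is too near 0 to decide on oocyte RNA. Without replicate 1 of 0 h the median was -1.32 and with library totals -1.89, with 13 of 13 called each time, so neither that library nor TMM scaling alone accounts for it. RNA quality and a change of the cells with time may each contribute, and neither was tested.

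The last pattern is the higher level of 6 erythroid transcripts in mural cells at 4 than at 0 h (median 2.41, lower quartile 2.39). A larger share of theca, stromal, smooth muscle and endothelial cells is argued against, since their 34 markers had a median of -0.14 and an upper quartile of 0.24. The 3 neutrophil markers measured were higher too (median 4.72, or 4.02 at their bound). Red blood cells in the libraries may be the source: over 9 mural libraries the log2 ratio of Hba-a1 to Hbb-bs had an SD of 0.0773, against 1.23 for log2 Hbb-bs. Whether more blood followed hCG or the dissection was not tested.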

How the results depend on the processing

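Alternatives on oocyte RNA, mitochondrial genes and the pair of libraries came after the data were seen. Counts of genes are in the order mural 4 against 0, 12 against 0 and 12 against 4 h, the same for cumulus cells, cumulus against mural cells at 0, 4 and 12 h, and the difference between cell types to 4 and 12 h. Within 1.5 times the reported count stayed all counts with other scaling, filters or tests and with thinning. With a 2-fold minimum they were 4519, 4152, 2981, 5043, 8450, 7311, 4679, 5927, 3799, 1628 and 4965, since that test asks for more. With only the compared libraries in the fit 5509 remained for cumulus 4 against 0 h and 1564 for the difference at 4 h, and the cause was not tested. With the oocyte sum as a covariate cumulus 12 against 0 h gave 6701, 12 against 4 h 4288, the cell types at 4 h 5662 and the difference at 12 h 4831. For cumulus cells at 12 h and between cell types at 4 h that fit extrapolates.

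Leaving out 1 library gave 7457 to 8285, 6640 to 7338, 5479 to 6080, 8456 to 10315, 11887 to 12708, 11091 to 12262, 7443 to 9228, 9606 to 11199, 6099 to 6660, 2037 to 4272 and 6896 to 8179 genes. The value 4272, without replicate 2 of the cumulus cells at 4 h, alone moved by over 1.5 times, and the cause was not tested. Libraries of one replicate number did not all deviate together: 9 of 45 pairs correlated by over 0.1 (-0.29 to 0.4), and 10 of 18 libraries matched best one of their own number. With the replicate block the counts were 9191, 8267, 7017, 9592, 12777, 12098, 9550, 10879, 7891, 2934 and 8157.

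With size factors, library totals, a library left out, the covariate and no oocyte-linked genes, 0, 3, 35, 39 and 18 list calls ended and 4, 12, 70, 23 and 3 were added. The replicate block ended 2 (adjusted p = 0.0599 and 0.0723) and added 3 (0.0498, 0.0487 and 0.0387). List calls with an estimated correlation numbered 2, 7, 0, 1, 0, 0, 3, 7, 2, 0 and 0, by the construction of that test, where 8, 12, 6, 6, 9, 5, 7, 8, 6, 1 and 1 had an unadjusted p under 0.05. Fry, which asks another question, gave 23 for cumulus 12 against 4 h, 27 and 26 between cell types at 0 and 4 h and 15 for the difference at 12 h.

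Of 699 values of named genes, 675 were called, and 620 of these kept direction and call in every alternative set at the outset except the 2-fold minimum. Under the covariate 616 kept both, 68 lost their call, 2 gained one and 13 turned direction, and the cause was not tested. Those were Bub1b (0.22), Syt1 (1.79) and Syt2 (2.08) in cumulus 12 against 0 h, and Ereg (-0.59), Adamts1 (-1.26), Il6 (-0.19), Runx1 (-0.58) and Cebpb (-0.51) in cumulus 12 against 4 h. Between cell types they were Plat (-0.7) at 4 h and Ldha (-0.35), Bub1b (0.57), Pcna (0) and Gja4 (0.01) at 12 h. Depth limits genes with few counts.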

Other observations

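No test here was planned, and genes were chosen after their values were seen. Levels are mean CPM of 3 libraries at 0, 4 and 12 h. The neurotensin gene Nts stood at 0.091, 857 and 21.9 in mural and 0, 249 and 210 in cumulus cells. Pdcd1, a receptor of T cells, stood at 0.342, 1.89 and 7.56 in mural and 0.111, 8.48 and 314 in cumulus cells.

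The responses of both cell types overlapped. At 4 h 3175 genes were higher than at 0 h in both, against 1138 if they were independent, and 2983 lower, against 1012. In mural cells 122 were higher and 100 lower that went the other way in cumulus cells. At 12 h 3245 were higher in both (1346 if independent) and 2498 lower (1251), and 302 and 376 went opposite ways. Across 19941 genes, which are not independent replicates, Spearman's rho between the changes was 0.55 at 4 h and 0.59 at 12 h. The contrasts share no library, and no cause of the overlap was tested.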
